A study of Escherichia coli with 12 samples.

How the data were processed

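RNA sequencing libraries from 12 samples of Escherichia coli were analysed, 3 for each of the strains labelled WT, gKO, aKO-6PGDf and aKO-Rescue, all exposed to heat shock at 45 °C per the labels. Total RNA was extracted with an RNeasy Protect Bacteria kit and libraries were made with a KAPA Hyper kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.11b, featureCounts and Subread 2.0.6, with genome build ASM584v2. The strand setting, the treatment of reads that map to several places and any depletion of ribosomal RNA are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies are uncertain.

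The deposited table gives TPM for 4638 genes in each library, as made by the authors, and each column sums to 1000000. TPM divides reads by gene length and by the library's total, so a gene's value depends on the share taken by all other genes. Columns were matched to samples by name, and 0 columns of other samples were present. Gene symbols were matched to the RefSeq annotation of ASM584v2, by symbol for 4621 and by synonym for 15. For 4636 genes TPM times gene length was a whole multiple of a step in each library, within 0.05 of a read for 99.94% to 100.0% of the genes. This gave between 20276481 and 37061000 assigned reads per library. The recovered reads were used for depth, for counts of reads at single loci and for 1 alternative, and not for the main test. Where a strain had 0 reads of a gene, a floor of 3 reads per library was used to give a lower bound of the change. Such bounds cover counting error only, as reads were counted without molecular identifiers. Replicates of a strain differed by more than sampling noise in each pair, so none were merged. This was judged from the mean chi-square per gene on recovered reads, 14.5 to 381.2 over the pairs, without a p-value.

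Differential abundance was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1). Genes at a TPM of at least 1 in at least 3 libraries were kept, which left 4404. Each library was rescaled so that its median log2 ratio to the mean library was 0. All 12 libraries entered 1 fit with a term for strain, followed by empirical Bayes moderation with a trend and robust settings, and 6 comparisons between strains were taken from it. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. The design allowed for a count table, and the branch for TPM applied. Gene groups were 42 lists fixed before the data were examined, tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of list members adjusted over the list alone are also given.

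Named genes followed a rule set before the data were examined. First came gnd and its chromosomal neighbours. Then, in each comparison, came up to 8 genes with the largest increase and up to 8 with the largest decrease among those that passed the test, whose 3 libraries in 1 strain all lay on 1 side of those of the other and whose mean over the 12 libraries was at least 5 TPM, with the last 4 of each side left to the counts where the text is long. From each list up to 4 members with the smallest adjusted p were taken, or up to 2 as values where none passed. Genes outside the rule are said to have been chosen after their values were seen.

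The procedure was tested on simulated data with 200 changed genes per strain among 4345 tested. For gKO against WT it recovered 82.1% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold, with 4.1% of calls false. For aKO-Rescue against WT it recovered 91% at 1.5-fold, with 6.3% of calls false, and for aKO-6PGDf against WT 92.5%, with 6.7% false. The simulation gave every gene and strain 1 dispersion, 0.00821, and set the direction of each change at random. In the data 43% to 64.8% of the tested genes were called and the spread differed between strains, so these rates may not carry over. Alternatives planned before the data were examined were the values as deposited, no filter, limma without a trend, a replicate block, only the libraries of the 2 strains compared, leaving out ribosomal and transfer RNA genes, leaving out the gnd region, pseudocounts of 0.1 and 5, leaving out each library in turn, a minimum change of 2-fold and an estimated correlation for lists. Library weights per strain, limma voom on recovered reads and the overlaps with the values as deposited were added after the data were seen. Overlaps between comparisons that share libraries were set against 50 simulations of unchanged groups. Figures and summaries were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.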

Results

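RNA was sequenced from 12 samples of Escherichia coli exposed to 45 °C, 3 libraries for each of 4 strains labelled WT, gKO, aKO-6PGDf and aKO-Rescue. By the series description, mutant strains were altered at gnd, the gene of 6-phosphogluconate dehydrogenase in the oxidative branch of the pentose phosphate pathway. The study asked how GndA, a small peptide encoded inside gnd, affects the transcriptome in heat-shocked cells. The labels do not spell out the strain names or say what each strain carries, so the names are used here as given. GndA has no row of its own in the table, so a read from its coding sequence counts as gnd. Whole reads could be recovered from the deposited TPM values, and they came to between 20276481 and 37061000 assigned reads per library. Values in TPM are means ± SD over the 3 libraries of a strain (n = 3), and log2 fold changes are given ± SE on the log2(TPM + 1) scale, which understates the change of genes with few reads. Adjusted p-values come from limma with Benjamini-Hochberg adjustment. The labels do not say that the 3 libraries of a strain came from separate cultures, so the p-values measure only the spread between these samples. Positions refer to the chromosome of strain K-12 MG1655 in assembly ASM584v2.

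The gnd transcript (b2029, positions 2099862 to 2101268) was examined first. It was at 649 ± 7.87 TPM in WT and at 0.127 ± 0.0152 TPM in gKO, where 6, 8 and 6 reads were found in the 3 libraries, a ratio of 5130 between the means. In aKO-6PGDf it was at 450 ± 26.8 TPM, lower than in WT (-0.71 ± 0.17, adjusted p = 0.00657). In aKO-Rescue the 3 libraries gave 820, 494 and 461 TPM, and the difference from WT did not pass the test (-0.12 ± 0.17, adjusted p = 0.574). Replicate 1 decided this, since without it gnd was lower than in WT by -0.37 on the log2 scale with an adjusted p = 0.00136. The label gKO therefore goes with the loss of nearly all gnd reads in each of its 3 libraries. Among the genes around gnd, which build O-antigen precursors and sugar nucleotides, galF (b2042, 2113434 to 2114327) rose from 295 ± 16.5 TPM in WT to 493 ± 47.8 TPM in gKO (0.59 ± 0.13, adjusted p = 0.00308). Its neighbours rfbB (0.67 ± 0.14) and rfbD (0.54 ± 0.11) also rose in gKO, as did wzzB on the other side of gnd (0.36 ± 0.09), whereas glf fell (-0.46 ± 0.12). In gKO 4 of the 18 genes of this neighbourhood were higher and 5 lower, gnd among them (4 higher and 5 lower adjusted over the list alone). Camera gave the gnd neighbourhood list an adjusted p = 0.836, and an adjusted p = 0.977 with an estimated correlation. Without rescaling, on the values as deposited, 6 were higher and 2 lower. In aKO-6PGDf 15 of the 18 genes of this neighbourhood were lower than in WT and 0 were higher (0 higher and 15 lower adjusted over the list alone), with wbbK at -1.08 ± 0.11, glf at -0.99 ± 0.12 and rfbX at -1.03 ± 0.13. For the gnd neighbourhood list camera gave an adjusted p = 3.9e-05, with adjusted p = 0.683 with an estimated correlation. In aKO-Rescue 9 of them were lower than in WT and 0 higher (0 higher and 9 lower adjusted over the list alone). The gnd neighbourhood list had a camera adjusted p = 0.0488, and adjusted p = 0.815 with an estimated correlation. This call was lost without rRNA and tRNA genes (0.0543), without aKO-Rescue replicate 3 (0.0645) and without WT replicate 1 (0.0536) or 2 (0.0548).

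**Figure D1:**
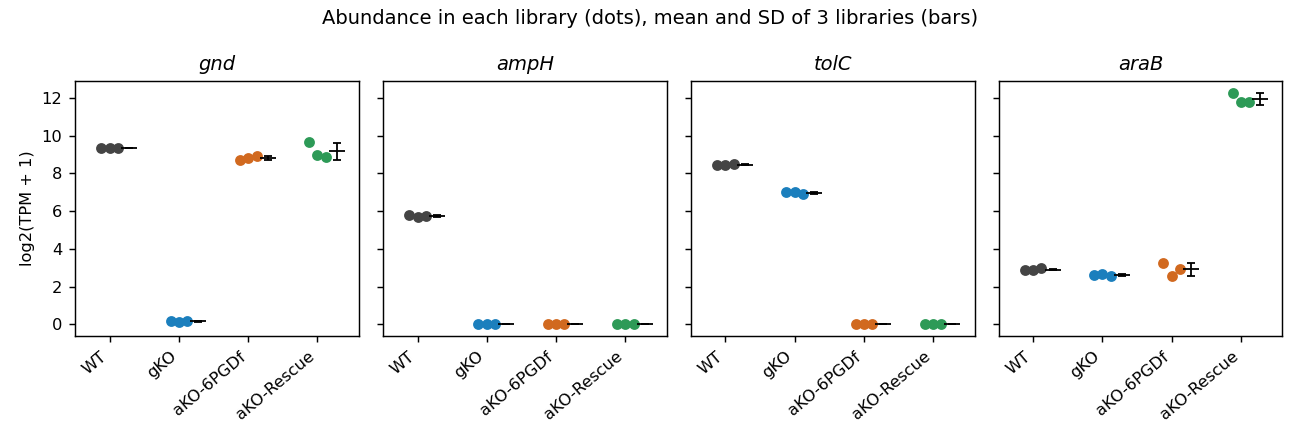
Each panel plots log2(TPM + 1) of 1 gene in the 12 libraries, as dots by strain, with the mean and SD of the 3 libraries beside them. The gnd transcript is near 0 in gKO, ampH is at 0 in the 3 mutant strains, tolC is at 0 in aKO-6PGDf and aKO-Rescue, and araB is high in aKO-Rescue.

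Reads were also missing at loci away from gnd, and these were chosen after their values were seen except where a gene is among the largest changes. The gene ampH (b0376, 395130 to 396287), which encodes a penicillin-binding protein, had 2373, 1726 and 1698 reads in the WT libraries, at 52.8 ± 2.47 TPM, and 0 reads in each of the 9 mutant libraries. With a floor of 3 reads per library it was at least 739-fold lower in gKO, at least 626-fold lower in aKO-6PGDf and at least 813-fold lower in aKO-Rescue. The adjacent genes iprA (b0375, 394506 to 395129) and sbmA (b0377, 396639 to 397859), the latter encoding a peptide transporter, had 37, 29 and 20 and 574, 481 and 411 reads in WT. In the mutant libraries iprA had 0 reads, and sbmA had 0 reads except for 3 reads in aKO-6PGDf replicate 2. The next gene, yaiW (397872 to 398966), was at 25 ± 0.469 TPM in WT and remained detectable at 1.47 ± 0.079 TPM in gKO, 2.7 ± 1.24 TPM in aKO-6PGDf and 1.01 ± 0.185 TPM in aKO-Rescue. Further out, ddlA had 162 ± 5.26 TPM in WT, 150 ± 10.8 TPM in gKO, 157 ± 5.97 TPM in aKO-6PGDf and 93.3 ± 11.2 TPM in aKO-Rescue. On the other side the pseudogene yaiT had 4.82 ± 0.407 TPM in WT, 2.54 ± 0.384 TPM in gKO, 2.06 ± 0.314 TPM in aKO-6PGDf and 1.93 ± 0.0944 TPM in aKO-Rescue. The gene tolC (b3035, 3178115 to 3179596), encoding the outer membrane channel of several efflux pumps, had 18725, 15343 and 14923 reads in WT and 0 reads in each library of aKO-6PGDf and aKO-Rescue. It was at least 5326-fold lower than in WT in aKO-6PGDf and at least 6921-fold lower in aKO-Rescue. In gKO tolC was at 125 ± 4.86 TPM, against 351 ± 9.87 TPM in WT. The genes on either side of tolC kept reads in every library, but their levels differed between strains. The gene nudF was at 54 ± 4.32 TPM in WT, 23.5 ± 2.23 TPM in gKO, 27.9 ± 2.84 TPM in aKO-6PGDf and 20 ± 1.31 TPM in aKO-Rescue, and ygiB at 395 ± 11.3 TPM, 411 ± 4.39 TPM, 594 ± 26.4 TPM and 325 ± 26.7 TPM in the same order.

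**Figure D2:**
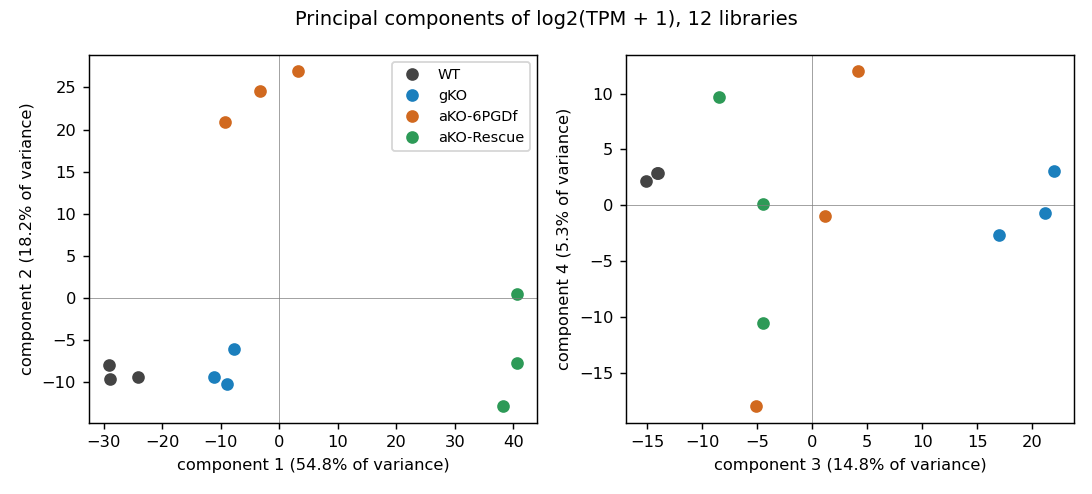
The panels plot the 12 libraries on the first 4 principal components of log2(TPM + 1), coloured by strain, with each component's share of the variance on its axis. Component 1 holds 54.8% of the variance and sets the aKO-Rescue libraries, at 38.2 to 40.6, apart from the WT libraries, at -29.1 to -24.2.

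The comparison of gKO with WT asks what changes in the strain that lost nearly all gnd reads. Genes of the RpoS general stress response rose in gKO, led by katE (1.44 ± 0.08, adjusted p = 5.6e-07), the catalase HPII, and by otsA (1.3 ± 0.08) and otsB (1.34 ± 0.11), which make trehalose. Genes of acid resistance fell, including the periplasmic chaperones hdeA (-3.34 ± 0.24, adjusted p = 4.0e-06) and hdeB (-2.89 ± 0.25), the lipoprotein gene slp (-2.37 ± 0.18) and the glutamate decarboxylase gene gadB (-3.07 ± 0.28). The dipeptide transporter genes dppC (2.51 ± 0.2, adjusted p = 5.6e-06) and dppD (2.44 ± 0.21) rose, with dppC at 159 ± 17.2 TPM against 24.2 ± 1.34 TPM. Of the 26 RpoS genes, 19 were higher and 1 was lower (19 higher and 1 lower adjusted over the list alone). Camera gave the RpoS list an adjusted p = 1.3e-06, and an adjusted p = 0.846 with an estimated correlation. Of the 14 acid resistance genes, 12 were lower and 1 was higher (2 higher and 12 lower adjusted over the list alone). Camera gave the acid resistance list an adjusted p = 6.9e-05, and an adjusted p = 0.846 with an estimated correlation.

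Of the lists of energy metabolism, some passed as lower in gKO. Respiratory complex I genes were lower in 7 of 13 cases and higher in 0 (0 higher and 7 lower adjusted over the list alone). Camera gave the complex I list an adjusted p = 0.0326, and an adjusted p = 0.977 with an estimated correlation. This call was lost with the values as deposited (0.06), where 1 complex I gene was lower and 0 higher. It was also lost without gKO replicate 3 (0.08) and without WT replicate 1 (0.0542) or 3 (0.0784). Genes of NADPH and NADH balance were lower in 6 of 9 cases and higher in 1 (1 higher and 6 lower adjusted over the list alone), a call lost without the gnd region (0.102). The list includes gnd itself, and its mean log2 fold change was -1.34 against a median of -0.37. The call therefore partly repeats the loss of gnd reads. Camera gave the NADPH and NADH balance list an adjusted p = 0.0153, and an adjusted p = 0.846 with an estimated correlation. Of 11 genes of terminal oxidases and other dehydrogenases, 7 were lower and 0 higher (0 higher and 7 lower adjusted over the list alone). Camera gave the terminal oxidase list an adjusted p = 0.0273, and an adjusted p = 0.846 with an estimated correlation. In the fit of gKO and WT alone this call was lost (0.106), and as deposited 3 were higher and 7 lower. Glycolysis (camera adjusted p = 0.638), the citric acid cycle (0.139) and anaerobic respiration (0.259) did not pass. Both the citric acid cycle (0.042) and anaerobic respiration (0.0427) passed as lower with the values as deposited, as did the citric acid cycle in a fit of gKO and WT alone (0.00844) and without aKO-Rescue replicate 1 (0.0196). Among the oxidase genes, those of the cytochrome bo operon fell, with cyoE at -1.34 ± 0.11, adjusted p = 5.1e-06, cyoD at -1.35 ± 0.13, cyoC at -1.27 ± 0.13 and cyoB at -1.15 ± 0.15. Of the 9 ATP synthase genes, 8 were lower and 0 were higher (0 higher and 8 lower adjusted over the list alone), with atpC at -0.81 ± 0.07 and atpD at -0.73 ± 0.08. Camera gave the ATP synthase list an adjusted p = 0.00345, and an adjusted p = 0.846 with an estimated correlation. Of the 33 genes for uptake of maltose, glycerol and other sugars under CRP control, 15 were lower and 1 was higher (1 higher and 15 lower adjusted over the list alone), with the maltose-binding protein gene malE at -1.72 ± 0.24 and gatY at -0.89 ± 0.13. Camera gave the sugar uptake list an adjusted p = 0.00201, and an adjusted p = 0.846 with an estimated correlation. Of the 41 flagellar and chemotaxis genes, 17 were lower and 1 was higher (1 higher and 17 lower adjusted over the list alone), with flgB at -0.98 ± 0.12. The flgB transcript was low, at 0.935 ± 0.0932 TPM in gKO and 2.63 ± 0.646 TPM in WT. Camera gave the flagellar list an adjusted p = 0.0153, and an adjusted p = 0.846 with an estimated correlation. Only 8 flagellar genes were lower, and 2 higher, with the values as deposited. The Cpx envelope stress genes went the other way. Of 12, 6 were higher and 0 were lower (9 higher and 0 lower adjusted over the list alone), with the periplasmic chaperones cpxP at 1.42 ± 0.1 and spy at 0.97 ± 0.13. Camera gave the Cpx list an adjusted p = 0.00742, and an adjusted p = 0.846 with an estimated correlation. As deposited, 10 Cpx genes were higher and 0 lower. The sigma 32 heat shock genes, of which 11 of 27 were higher and 8 lower, did not pass as a list (11 higher and 8 lower adjusted over the list alone). Camera gave the sigma 32 list an adjusted p = 0.926, and an adjusted p = 0.977 with an estimated correlation. As deposited, 12 sigma 32 genes were higher and 4 lower. Genes of the pentose phosphate pathway did not pass as a list either, with 4 of 10 higher and 3 lower (4 higher and 4 lower adjusted over the list alone). Camera gave the pentose phosphate list an adjusted p = 0.907, and an adjusted p = 0.977 with an estimated correlation. Among the largest single changes, the serine and threonine degradation regulator gene tdcA fell (-3.58 ± 0.34, adjusted p = 2.5e-05), ychH was at -2.81 ± 0.19, and exoD, annotated as a pseudogene, was at 88.8 ± 11.1 TPM against 4.21 ± 0.481 TPM (3.97 ± 0.97, adjusted p = 0.00778). The nitrite reductase assembly gene nrfF was at 2.49 ± 0.67, adjusted p = 0.0128. On recovered reads with voom, neither exoD (adjusted p = 0.0711) nor nrfF (adjusted p = 0.0526) passed. The nrfF libraries of gKO differed, at 51.5 ± 42.6 TPM against 5.69 ± 2.71 TPM in WT. Those of exoD were close within gKO and within WT, but the aKO-6PGDf libraries, which enter the shared fit, gave 4.24, 133 and 74 TPM. In all, 2122 of 4404 tested genes passed the test, 1100 higher and 1022 lower, and 311 of them changed at least 2-fold. With the values as deposited, without rescaling, 71.3% of the genes that passed were higher, against 51.8% here. Rescaling moved the median of all genes by 0.15 in this comparison, by 0.18 in aKO-6PGDf against WT, by -0.07 in aKO-Rescue against WT, by -0.24 in aKO-Rescue against aKO-6PGDf, by 0.03 in aKO-6PGDf against gKO and by -0.22 in aKO-Rescue against gKO, on the log2 scale and given as deposited minus rescaled. Transfer RNA genes took 5.0% to 5.9% of TPM in gKO and 2.9% to 3.4% in WT.

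**Figure D3:**
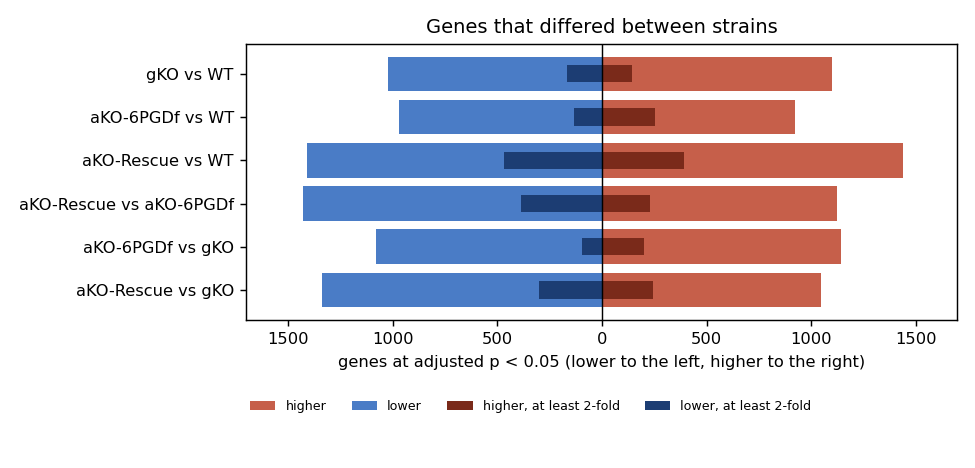
Bars give the number of genes at adjusted p < 0.05 in each of the 6 comparisons, higher to the right and lower to the left, with genes changed at least 2-fold as the inner bars. The longest bars belong to aKO-Rescue against WT, with 1442 genes higher and 1412 lower.

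The comparison of aKO-6PGDf with WT asks what changes in a strain that keeps most gnd reads. Genes of the RpoS response rose, with the pyruvate oxidase gene poxB at 2.7 ± 0.09, adjusted p = 4.2e-09, ybgA at 2.05 ± 0.07, katE at 2.1 ± 0.08 and otsA at 2.04 ± 0.08. Outer membrane porin genes fell, with ompF at 48.1 ± 4.95 TPM against 872 ± 118 TPM (-4.33 ± 0.11, adjusted p = 6.3e-10), nmpC at -4.69 ± 0.18 and ompC at -0.94 ± 0.08, as did the outer membrane protease gene ompT (-2.61 ± 0.1). The Cpx envelope stress genes spy (2.99 ± 0.13, adjusted p = 1.9e-08) and cpxP (2.12 ± 0.1) rose. These changes stood beside the absence of tolC and ampH reads in this strain. Of 26 RpoS genes, 24 were higher and 1 was lower (24 higher and 1 lower adjusted over the list alone). For the RpoS list camera gave an adjusted p = 8.3e-16, with adjusted p = 0.239 with an estimated correlation. Of 12 Cpx genes, 9 were higher and 0 were lower (10 higher and 0 lower adjusted over the list alone). For the Cpx list camera gave an adjusted p = 1.4e-05, with adjusted p = 0.683 with an estimated correlation. Of 23 lipopolysaccharide and outer membrane genes, 10 were lower and 2 were higher (2 higher and 10 lower adjusted over the list alone). For the outer membrane list camera gave an adjusted p = 0.00434, with adjusted p = 0.683 with an estimated correlation. The values as deposited gave 6 outer membrane genes lower and 4 higher.

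Ribosomal protein genes were lower in aKO-6PGDf, 38 of 54 with 0 higher (0 higher and 40 lower adjusted over the list alone), among them rpmD (-1.08 ± 0.09) and rpmJ (-0.96 ± 0.08). For the ribosomal protein list camera gave an adjusted p = 3.7e-11, with adjusted p = 0.683 with an estimated correlation. As deposited, 27 were lower and 0 higher. Genes of the oxidative stress regulators SoxRS and OxyR rose, 10 of 20 with 1 lower (10 higher and 1 lower adjusted over the list alone). For the oxidative stress list camera gave an adjusted p = 0.00181, with adjusted p = 0.683 with an estimated correlation. They included the activator genes marA (1.94 ± 0.1, adjusted p = 6.1e-08) and soxS (1.67 ± 0.1), as well as inaA (2.07 ± 0.11). The SOS genes of the DNA damage response rose in 12 of 15 cases and fell in 0 (13 higher and 0 lower adjusted over the list alone), with recN at 0.96 ± 0.12, uvrB at 0.42 ± 0.05 and the division inhibitor gene sulA at 0.84 ± 0.13. For the SOS list camera gave an adjusted p = 0.000273, with adjusted p = 0.683 with an estimated correlation. Of 17 genes for the exopolysaccharide colanic acid, 13 were higher and 0 were lower (16 higher and 0 lower adjusted over the list alone), with rcsA at 0.83 ± 0.17 and wza at 1.35 ± 0.3. The wza transcript was low and its aKO-6PGDf libraries differed, at 5.18 ± 3.85 TPM against 0.986 ± 0.288 TPM in WT. For the colanic acid list camera gave an adjusted p = 0.000655, with adjusted p = 0.683 with an estimated correlation. Glycolysis genes were higher in 11 of 18 cases and lower in 0 (12 higher and 0 lower adjusted over the list alone), with fbaB at 1.5 ± 0.07, ptsG at 0.8 ± 0.09 and pfkA at 0.93 ± 0.11. For the glycolysis list camera gave an adjusted p = 0.00286, with adjusted p = 0.683 with an estimated correlation. The sigma 32 heat shock genes passed as a list here, 15 of 27 higher and 4 lower (15 higher and 4 lower adjusted over the list alone), with prlC at 0.78 ± 0.05 and hslV at 0.68 ± 0.06. For the sigma 32 list camera gave an adjusted p = 0.0101, with adjusted p = 0.683 with an estimated correlation. Acid resistance genes were again lower, 12 of 14 with 1 higher (1 higher and 12 lower adjusted over the list alone), and hdeA was at -1.77 ± 0.24. For the acid resistance list camera gave an adjusted p = 0.000359, with adjusted p = 0.683 with an estimated correlation. The ATP synthase genes were lower in 7 of 9 cases and higher in 0 (0 higher and 8 lower adjusted over the list alone). For the ATP synthase list camera gave an adjusted p = 0.00057, with adjusted p = 0.683 with an estimated correlation. Genes of maltose and related sugars were lower in 15 of 33 cases and higher in 2 (2 higher and 17 lower adjusted over the list alone), with lamB at -2.16 ± 0.21. For the sugar uptake list camera gave an adjusted p = 0.00434, with adjusted p = 0.683 with an estimated correlation. The largest increase among genes at a mean of at least 5 TPM was that of yhcN (3.91 ± 0.2, adjusted p = 1.0e-07), followed by spy and by the nitrite reductase genes nirB (2.97 ± 0.86, adjusted p = 0.0196) and nirD (2.86 ± 0.79, adjusted p = 0.016), for which the 3 libraries differed, nirB being at 36.8, 264 and 126 TPM. Without aKO-6PGDf replicate 2 neither nirB (adjusted p = 0.0663) nor nirD (adjusted p = 0.0564) passed, and nirB was also lost without aKO-6PGDf replicate 3 (adjusted p = 0.0547), WT replicate 1 (adjusted p = 0.0529) or WT replicate 3 (adjusted p = 0.0536). On recovered reads with voom nirD was lost as well (adjusted p = 0.0785). In all, 1895 genes passed the test, 924 higher and 971 lower, 392 of them at least 2-fold. With the values as deposited 74.6% were higher, against 48.8% here. The replicates of aKO-6PGDf varied more than those of the other strains, with a median SD of 0.147 on the log2 scale against 0.091 in WT, 0.084 in gKO and 0.11 in aKO-Rescue.

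The comparison of aKO-Rescue with WT showed the largest number of differences. The arabinose genes were the most raised, with the ribulokinase gene araB (b0063, 68348 to 70048) at 3950 ± 859 TPM against 6.51 ± 0.261 TPM in WT (9.09 ± 0.16, adjusted p = 3.9e-12), araA at 8.59 ± 0.11, araD at 8.52 ± 0.13 and the binding protein gene araF at 6.49 ± 0.12. The genes araE, araG, araJ and araH, which lie apart from araBAD and serve uptake or export, were raised by 5.96, 5.61, 5.46 and 5.4. Genes of the maltose system fell, with malK at -6.74 ± 0.26, adjusted p = 7.5e-09, malE at -6.23 ± 0.24 and lamB at -6.16 ± 0.21, and so did the serine and threonine degradation genes tdcB (-7.25 ± 0.27), tdcA (-7.19 ± 0.34), tdcC (-6.55 ± 0.29) and tdcD (-6.29 ± 0.31). Of 33 genes of maltose and related sugars, 25 were lower and 2 were higher (3 higher and 25 lower adjusted over the list alone). The sugar uptake list had a camera adjusted p = 1.5e-06, and adjusted p = 0.596 with an estimated correlation. Ribosomal protein genes were higher, 52 of 54 with 0 lower (52 higher and 0 lower adjusted over the list alone), among them rplE (1.04 ± 0.09, adjusted p = 2.5e-06) and rpmA (1.1 ± 0.11). The ribosomal protein list had a camera adjusted p = 1.2e-10, and adjusted p = 0.683 with an estimated correlation. Acid resistance genes were lower, 13 of 14 with 0 higher (0 higher and 13 lower adjusted over the list alone), and hdeA was at 34.9 ± 5.05 TPM against 1180 ± 149 TPM (-4.98 ± 0.24). The acid resistance list had a camera adjusted p = 6.3e-06, and adjusted p = 0.683 with an estimated correlation.

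Several smaller groups also differed between aKO-Rescue and WT. Purine and pyrimidine synthesis genes were higher in 16 of 22 cases and lower in 2 (16 higher and 2 lower adjusted over the list alone), with purE at 1.98 ± 0.15, purK at 1.91 ± 0.16 and purM at 2.19 ± 0.19. The nucleotide synthesis list had a camera adjusted p = 0.00219, and adjusted p = 0.815 with an estimated correlation. Genes of the magnesium-responsive PhoPQ system were higher in 10 of 12 cases and lower in 2 (10 higher and 2 lower adjusted over the list alone), with the magnesium transporter gene mgtA at 3.31 ± 0.18, adjusted p = 6.2e-08 and phoQ at 1.3 ± 0.07. The PhoPQ list had a camera adjusted p = 0.002, and adjusted p = 0.596 with an estimated correlation. The sigma 32 heat shock genes were higher in 19 of 27 cases and lower in 4 (19 higher and 4 lower adjusted over the list alone), with hslV at 0.97 ± 0.06, htpX at 0.99 ± 0.06 and htpG at 0.95 ± 0.07, while hslJ was at -1.17 ± 0.07. The sigma 32 list had a camera adjusted p = 0.00409, and adjusted p = 0.596 with an estimated correlation. Glycolysis genes were lower in 15 of 18 cases and higher in 1 (1 higher and 15 lower adjusted over the list alone), led by pykA (-1.15 ± 0.07). The glycolysis list had a camera adjusted p = 0.00146, and adjusted p = 0.683 with an estimated correlation. Gluconate and Entner-Doudoroff genes were lower in 12 of 17 cases and higher in 1 (1 higher and 12 lower adjusted over the list alone), with kdgK at -1.36 ± 0.1 and gntT at -1 ± 0.12. The gluconate list had a camera adjusted p = 0.00943, and adjusted p = 0.596 with an estimated correlation. Histidine synthesis genes were lower in 8 of 9 cases and higher in 0 (0 higher and 8 lower adjusted over the list alone), with hisG at -0.76 ± 0.08. The histidine list had a camera adjusted p = 0.00652, and adjusted p = 0.725 with an estimated correlation. Against WT, marA was at 2.64 ± 0.1 and ompF at -3.71 ± 0.11, in a strain that, like aKO-6PGDf, had no tolC reads. In all, 2854 genes passed the test, 1442 higher and 1412 lower, and 861 of them changed at least 2-fold. Transfer RNA genes took 5.7% to 6.4% of TPM in aKO-Rescue.

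**Figure D4:**
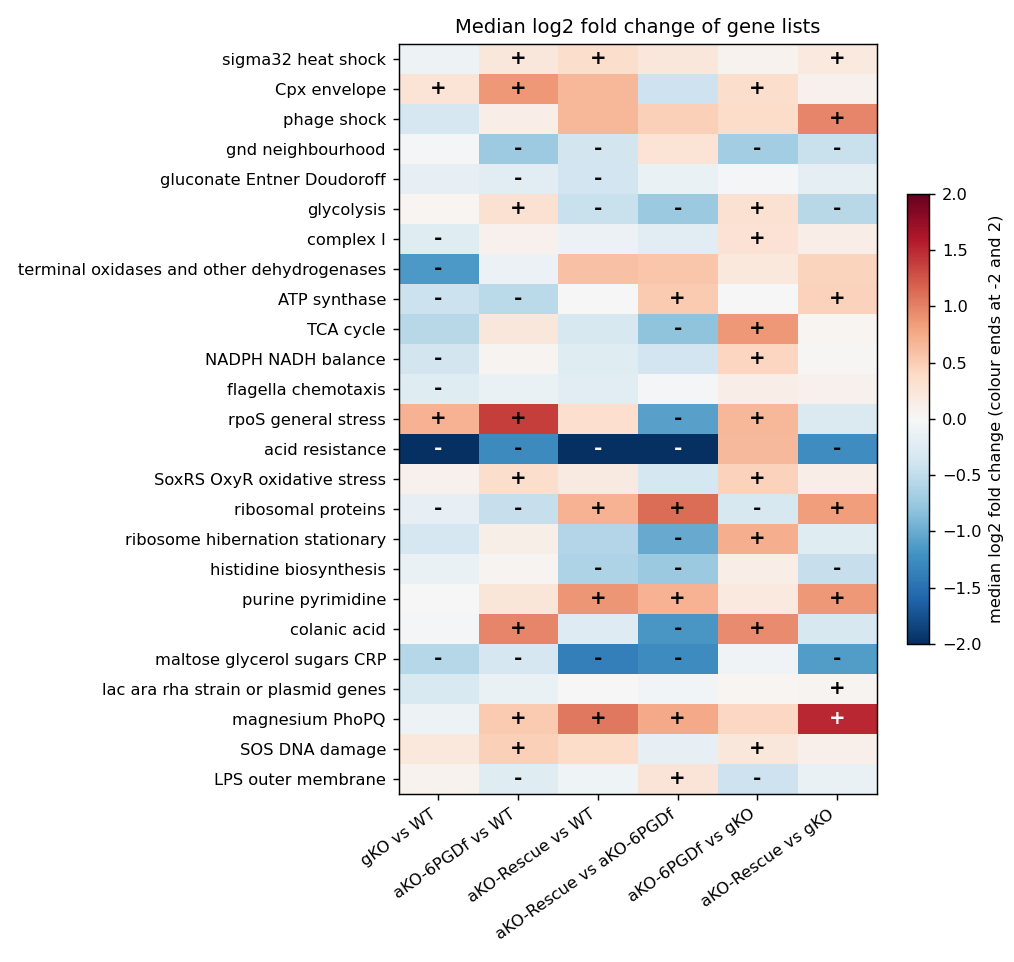
Colour gives the median log2 fold change of each gene list in each of the 6 comparisons, for lists that passed the camera test in at least 1 of them, and + or - marks a list that passed as higher or lower. Some marked lists are given only here. No list passed with an estimated correlation. Of the 73 marked medians, 2 changed sign with the values as deposited, both in aKO-Rescue against gKO, namely that of the sigma 32 list, to -0.02, and that of the lactose, arabinose and rhamnose list, to -0.04. Of the 77 unmarked medians, 18 changed sign.

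The direct comparison of aKO-Rescue with aKO-6PGDf tests what differs between the 2 strains that share aKO in their labels. The arabinose genes again led the increases, with araB at 9.23 ± 0.16, adjusted p = 5.0e-12, araA at 8.73 ± 0.11, araD at 8.41 ± 0.13 and araF at 6.5 ± 0.12. Every ribosomal protein gene tested, 54 of 54, was higher in aKO-Rescue (54 higher and 0 lower adjusted over the list alone), with rpmD at 1.8 ± 0.09 and rplE at 1.58 ± 0.09. In camera the ribosomal protein list had an adjusted p = 1.5e-23, or adjusted p = 0.41 with an estimated correlation. RpoS genes were lower, 24 of 26 with 0 higher (0 higher and 26 lower adjusted over the list alone), including osmC (-2.31 ± 0.09, adjusted p = 1.1e-08), the DNA-binding protein gene dps (-1.54 ± 0.07) and hchA (-1.99 ± 0.09). In camera the RpoS list had an adjusted p = 1.0e-09, or adjusted p = 0.41 with an estimated correlation. Glycolysis genes were lower in 17 of 18 cases and higher in 0 (0 higher and 17 lower adjusted over the list alone), with fbaB at -1.83 ± 0.07 and ptsG at -1.4 ± 0.09. In camera the glycolysis list had an adjusted p = 5.5e-07, or adjusted p = 0.41 with an estimated correlation. Colanic acid genes were lower in 17 of 17 cases (0 higher and 17 lower adjusted over the list alone), with wcaA at -1.63 ± 0.25 and wza at -1.71 ± 0.3. Both were low, with wcaA at 0.711 ± 0.0876 TPM in aKO-Rescue against 5.39 ± 3.34 TPM in aKO-6PGDf. In camera the colanic acid list had an adjusted p = 0.00148, or adjusted p = 0.605 with an estimated correlation. Maltose and related genes were lower in 24 of 33 cases and higher in 0 (0 higher and 24 lower adjusted over the list alone), with malK at -4.63 ± 0.26 and malE at -4.17 ± 0.24. In camera the sugar uptake list had an adjusted p = 7.6e-06, or adjusted p = 0.605 with an estimated correlation. The tdcA (-4.6 ± 0.34) and tdcB (-4.52 ± 0.27) transcripts also fell. Acid resistance genes were lower in 13 of 14 cases (0 higher and 13 lower adjusted over the list alone), with hdeA at -3.21 ± 0.24. In camera the acid resistance list had an adjusted p = 3.4e-05, or adjusted p = 0.605 with an estimated correlation. The ribosome hibernation genes raiA (-2.65 ± 0.14) and rmf (-1.01 ± 0.07) fell, as did 4 of 5 genes of their list (0 higher and 4 lower adjusted over the list alone). In camera the hibernation list had an adjusted p = 0.0172, or adjusted p = 0.41 with an estimated correlation. The ATP synthase genes were higher in 9 of 9 cases (9 higher and 0 lower adjusted over the list alone). In camera the ATP synthase list had an adjusted p = 0.000957, or adjusted p = 0.605 with an estimated correlation. As deposited, 6 ATP synthase genes were higher and 0 lower. PhoPQ genes were higher in 9 of 12 cases and lower in 0 (10 higher and 0 lower adjusted over the list alone), with mgtL at 2 ± 0.16. In camera the PhoPQ list had an adjusted p = 0.00029, or adjusted p = 0.41 with an estimated correlation. Purine and pyrimidine genes were higher in 14 of 22 cases and lower in 1 (16 higher and 1 lower adjusted over the list alone). In camera the nucleotide synthesis list had an adjusted p = 0.000684, or adjusted p = 0.605 with an estimated correlation. Histidine synthesis genes were lower in 9 of 9 cases (0 higher and 9 lower adjusted over the list alone). In camera the histidine list had an adjusted p = 0.00293, or adjusted p = 0.605 with an estimated correlation. Among gnd and its neighbours, gnd itself was higher in aKO-Rescue (0.59 ± 0.17, adjusted p = 0.0121), together with rfbC (0.76 ± 0.13) and rfbX (0.72 ± 0.13). The values do not show whether the gnd reads of aKO-Rescue came from the chromosomal locus. The gnd neighbourhood had 8 genes higher and 3 lower and did not pass as a list (9 higher and 3 lower adjusted over the list alone). In camera the gnd neighbourhood list had an adjusted p = 0.102, or adjusted p = 0.639 with an estimated correlation. It passed as higher without aKO-6PGDf replicate 2 (0.0398). The call on gnd was lost with the values as deposited (adjusted p = 0.0925) and in a fit of the 6 libraries of these 2 strains alone (adjusted p = 0.0677). Without aKO-Rescue replicate 1 the change fell to 0.323 and still passed (adjusted p = 0.0039). In all, 2556 genes passed the test, 1126 higher and 1430 lower, and 615 changed at least 2-fold. With the values as deposited 25.4% of the genes that passed were higher, against 44.1% here.

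Of the 1895 genes that differed between aKO-6PGDf and WT, 681 moved in the opposite direction between aKO-6PGDf and aKO-Rescue, 612 moved further in the same direction and 602 did not pass the second test. Independent lists of these sizes would give 548 opposite and 552 in the same direction. Of genes higher in aKO-6PGDf than in WT, 431 were then lower in aKO-Rescue, against 300 for independent lists. Of genes lower in aKO-6PGDf, 250 were then higher in aKO-Rescue, against 248, and 404 were lower again, against 315. The split depends on the scaling. As deposited, 853 raised genes were then lower, against 722 for independent lists, 95 lowered genes were then higher, against 84, and 302 were lower again, against 246. The fold changes of the 2 comparisons had a correlation of -0.02 across genes, where unchanged groups sharing the aKO-6PGDf libraries gave -0.66 on average in 50 simulations, and a covariance of -0.013 against a simulated -0.03. Genes are not independent replicates, and the aKO-6PGDf libraries enter both comparisons, so part of the opposite moves may come from those shared libraries. The comparisons against WT overlapped in the same direction. Between gKO and aKO-6PGDf, 463 genes were higher in both and 540 lower in both, against 231 and 225 for independent lists, with a correlation of 0.57 (simulated 0.34) and a covariance of 0.22 (simulated 0.009). As deposited, 959 were higher and 273 lower in both, against 554 and 76, so the balance depends on the scaling. Between gKO and aKO-Rescue, 756 were higher and 720 lower in both, against 360 and 328, with a correlation of 0.58 (simulated 0.38) and a covariance of 0.347 (simulated 0.009). Without rescaling 870 were higher and 511 lower in both, against 463 and 224. Between aKO-6PGDf and aKO-Rescue, 621 were higher and 701 lower in both, against 303 and 311, with a correlation of 0.63 (simulated 0.26) and a covariance of 0.421 (simulated 0.009). Here the values as deposited gave 830 higher and 418 lower, against 448 and 184. With 3 WT libraries the controls could not be divided into groups of at least 2 libraries each, so part of these overlaps may come from the shared WT libraries. In all 3 mutant strains, 361 genes were higher and 449 lower than in WT.

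The comparison of aKO-6PGDf with gKO sets the strain that keeps most gnd reads against the strain that lost nearly all of them. The 2 strains also differ at tolC, which had reads in gKO and 0 reads in aKO-6PGDf. The differences below therefore cannot be assigned to gnd alone. Besides gnd itself (8.54 ± 0.17, adjusted p = 1.1e-10), RpoS genes were higher in aKO-6PGDf, 24 of 26 with 0 lower (25 higher and 0 lower adjusted over the list alone), including poxB (1.6 ± 0.09, adjusted p = 5.1e-07) and ybgA (1.09 ± 0.07). Camera gave the RpoS list an adjusted p = 8.5e-10, and an adjusted p = 0.611 with an estimated correlation. Genes of the citric acid cycle were higher in 16 of 18 cases and lower in 1 (17 higher and 1 lower adjusted over the list alone), with acnA at 1.12 ± 0.11 and fumC at 1.25 ± 0.17, whereas fumB was at -1.35 ± 0.3. Camera gave the citric acid cycle list an adjusted p = 0.00209, and an adjusted p = 0.611 with an estimated correlation. Genes of respiratory complex I were higher in 9 of 13 cases and lower in 0 (12 higher and 0 lower adjusted over the list alone), with nuoL at 0.41 ± 0.08. Camera gave the complex I list an adjusted p = 0.00397, and an adjusted p = 0.611 with an estimated correlation. SoxRS and OxyR genes were higher in 11 of 20 cases and lower in 0 (11 higher and 2 lower adjusted over the list alone), with inaA at 1.85 ± 0.11, soxS at 1.24 ± 0.1 and marA at 1.11 ± 0.1. Camera gave the oxidative stress list an adjusted p = 0.00209, and an adjusted p = 0.611 with an estimated correlation. Colanic acid genes were higher in 15 of 17 cases and lower in 0 (17 higher and 0 lower adjusted over the list alone), and glycolysis genes in 10 of 18 cases with 0 lower (12 higher and 0 lower adjusted over the list alone). Camera gave the colanic acid list an adjusted p = 0.00123, and an adjusted p = 0.611 with an estimated correlation. Camera gave the glycolysis list an adjusted p = 0.0124, and an adjusted p = 0.611 with an estimated correlation. Outer membrane genes were lower in 15 of 23 cases and higher in 2 (2 higher and 17 lower adjusted over the list alone), with ompF at -3.56 ± 0.11, adjusted p = 5.2e-09 and ompT at -1.1 ± 0.1. Camera gave the outer membrane list an adjusted p = 0.000298, and an adjusted p = 0.611 with an estimated correlation. Ribosomal protein genes were lower in 35 of 54 cases and higher in 0 (0 higher and 39 lower adjusted over the list alone), with rplX at -0.49 ± 0.08. Camera gave the ribosomal protein list an adjusted p = 2.3e-06, and an adjusted p = 0.611 with an estimated correlation. Around gnd, 13 of 18 genes were lower and 1, gnd, was higher (1 higher and 14 lower adjusted over the list alone), with rfbB at -1.3 ± 0.14 and galF at -1.01 ± 0.13. Camera gave the gnd neighbourhood list an adjusted p = 0.000422, and an adjusted p = 0.611 with an estimated correlation. The type 1 fimbria gene fimC (-2.67 ± 0.2), the porin gene nmpC (-2.91 ± 0.18) and adiY (-2.68 ± 0.3) fell, and tolC fell from 125 ± 4.86 TPM to 0 reads. The regulator gene cecR (3.14 ± 0.1) and yhcN (3.9 ± 0.2) rose. The nitrate transporter gene narK passed the test (5.36 ± 1.5, adjusted p = 0.0148), but its 3 aKO-6PGDf libraries gave 90.9, 1755 and 466 TPM and its gKO libraries 32.3, 4.68 and 4.28 TPM, and without gKO replicate 2 the call was lost (adjusted p = 0.0527). The sigma 32 heat shock genes did not pass as a list, with 11 of 27 higher and 2 lower (11 higher and 2 lower adjusted over the list alone). Camera gave the sigma 32 list an adjusted p = 0.0522, and an adjusted p = 0.611 with an estimated correlation. The list did pass as higher under 7 alternatives, namely as deposited (0.0291), without a filter (0.0434), with a pseudocount of 5 (0.0435), without gKO replicate 2 (0.0284), without aKO-6PGDf replicate 1 (0.0151) or 3 (0.0424) and with library weights per strain (0.0457), given as camera adjusted p. In all, 2220 genes passed the test, 1141 higher and 1079 lower, and 296 changed at least 2-fold.

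The comparison of aKO-Rescue with gKO shared its raised arabinose genes and its lower tdcB with the other comparisons of aKO-Rescue, but not its rise of gnd to this extent. The transcripts of araB (9.5 ± 0.16, adjusted p = 2.9e-12), gnd (9.13 ± 0.17, from 20 reads in gKO), araA (8.57 ± 0.11) and araD (8.13 ± 0.13) were the most raised, and tdcD (-5.52 ± 0.31, adjusted p = 2.4e-07), tdcB (-5.41 ± 0.27) and tdcC (-5.31 ± 0.29) fell, together with tolC, which had 0 reads in aKO-Rescue. All 54 of 54 ribosomal protein genes were higher (54 higher and 0 lower adjusted over the list alone), with rpmD at 1.37 ± 0.09 and rplO at 1.52 ± 0.11. For the ribosomal protein list camera gave an adjusted p = 2.3e-19, with adjusted p = 0.653 with an estimated correlation. PhoPQ genes were higher in 9 of 12 cases and lower in 0 (9 higher and 0 lower adjusted over the list alone), with slyB at 1.64 ± 0.07, adjusted p = 2.9e-08 and phoP at 1.55 ± 0.09. For the PhoPQ list camera gave an adjusted p = 4.9e-05, with adjusted p = 0.653 with an estimated correlation. Purine and pyrimidine genes were higher in 12 of 22 cases and lower in 1 (13 higher and 1 lower adjusted over the list alone), with purL at 2.24 ± 0.18. For the nucleotide synthesis list camera gave an adjusted p = 0.000264, with adjusted p = 0.655 with an estimated correlation. Among the heat shock genes, the chaperone genes ibpB (2.05 ± 0.1, adjusted p = 4.6e-08), dnaK (1.81 ± 0.11), ibpA (1.67 ± 0.11) and dnaJ (1.26 ± 0.07) were higher in aKO-Rescue. As a list, the sigma 32 genes were higher in 14 of 27 cases and lower in 4 (14 higher and 4 lower adjusted over the list alone). For the sigma 32 list camera gave an adjusted p = 0.00424, with adjusted p = 0.653 with an estimated correlation. This call was lost with the values as deposited, where 10 were higher, 9 lower, the median was -0.02 and the camera adjusted p = 0.0582. Acid resistance genes were lower in 14 of 14 cases (0 higher and 14 lower adjusted over the list alone), with gadE at -2.12 ± 0.29 and gadX at -1.27 ± 0.15. For the acid resistance list camera gave an adjusted p = 0.000264, with adjusted p = 0.655 with an estimated correlation. Maltose and related genes were lower in 25 of 33 cases and higher in 5 (6 higher and 25 lower adjusted over the list alone), with malM at -4.26 ± 0.18. For the sugar uptake list camera gave an adjusted p = 4.9e-05, with adjusted p = 0.653 with an estimated correlation. Glycolysis genes were lower in 14 of 18 cases and higher in 0 (1 higher and 15 lower adjusted over the list alone), with fbaB at -1.22 ± 0.07. For the glycolysis list camera gave an adjusted p = 0.000202, with adjusted p = 0.653 with an estimated correlation. The ATP synthase genes were higher in 8 of 9 cases and lower in 0 (9 higher and 0 lower adjusted over the list alone). For the ATP synthase list camera gave an adjusted p = 0.00155, with adjusted p = 0.655 with an estimated correlation. Around gnd, 11 of 18 genes were lower and 1, gnd, was higher (1 higher and 13 lower adjusted over the list alone). As deposited, 17 were lower and 1 higher. For the gnd neighbourhood list camera gave an adjusted p = 0.0395, with adjusted p = 0.695 with an estimated correlation. This call was lost without gKO replicate 2 (0.0746) and without aKO-Rescue replicate 1 (0.0933) or 3 (0.0665). In all, 2386 genes passed the test, 1047 higher and 1339 lower, and 548 changed at least 2-fold. With the values as deposited 24.3% of the genes that passed were higher, against 43.9% here.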

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

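The voom test on recovered reads, the library weights per strain and the overlaps with the values as deposited were chosen after the data were seen, and the other alternatives before. Apart from the minimum change of 2-fold, the counts of called genes ranged over the alternatives from 1713 to 2607 for gKO against WT, 1562 to 2061 for aKO-6PGDf against WT, 2623 to 2999 for aKO-Rescue against WT, 2178 to 2772 for aKO-Rescue against aKO-6PGDf, 1721 to 2273 for aKO-6PGDf against gKO and 2096 to 2599 for aKO-Rescue against gKO, each within 1.5 times the reported count. With a minimum change of 2-fold the counts were 311, 392, 861, 615, 296 and 548 in the same order, since this asks for a larger change. The gene lists called numbered 10, 15, 10, 13, 13 and 12 with the preset correlation. With an estimated correlation camera called 0, 0, 0, 0, 0 and 0, while 1, 1, 2, 5, 1 and 2 lists had an unadjusted p under 0.05 and fry called 20, 26, 27, 32, 26 and 26, which does not compare a list with other genes. Leaving out 1 library at a time gave 8 to 11, 14 to 18, 9 to 12, 12 to 16, 12 to 15 and 10 to 12 called lists. The replicate numbers did not pair the samples. Deviations of same-numbered libraries had correlations of -0.37 to 0.26 over 18 pairs, and 1 of 12 libraries correlated best with its own number. Differently numbered libraries reached -0.46 (aKO-6PGDf replicate 2 with aKO-Rescue replicate 3) and 0.49 (aKO-6PGDf replicate 1 with aKO-Rescue replicate 3). Whether strains shared a source of variation under other numbers was not tested. With a replicate block 2047, 1842, 2821, 2537, 2154 and 2351 genes were called. Of 3824 values of single genes under the alternatives, 3811 kept direction and side of the threshold, 11 lost the call, 1 gained it and 1 changed sign. That was gnd in aKO-Rescue against WT, not called, which moved from -0.12 to 0.038 without aKO-Rescue replicate 3, and the cause was not tested. Without aKO-Rescue replicate 1 it passed, at -0.37. Choices meant for a count table, including a comparison of units, did not apply to TPM and were not run. At 20276481 reads or more per library, genes that reached 1 TPM in fewer than 3 libraries were not tested.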

Other observations

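The tests of explanations below were all chosen after the results they address were seen, as were lacZ, araC and the exoD values of aKO-6PGDf. Some further genes of central metabolism and sugar use differed in aKO-Rescue. The transketolase gene tktA, of the non-oxidative pentose phosphate branch, was at 2650 ± 84.6 TPM in aKO-Rescue and 864 ± 8.57 TPM in WT (1.68 ± 0.11, adjusted p = 1.8e-07). The beta-galactosidase gene lacZ was at 65 ± 14.8 TPM against 318 ± 33 TPM (-2.23 ± 0.14, adjusted p = 1.6e-07), and the tryptophanase gene tnaA at 1000 ± 114 TPM against 11400 ± 1350 TPM (-3.44 ± 0.11, adjusted p = 2.0e-09). The arabinose regulator gene araC gave 872, 423 and 385 TPM in the aKO-Rescue libraries and 30.7, 35.6 and 31.6 TPM in WT. The pseudogene exoD gave 4.24, 133 and 74 TPM in the aKO-6PGDf libraries, 88.8 ± 11.1 TPM in gKO and 4.21 ± 0.481 TPM in WT.

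The arabinose genes were far higher in aKO-Rescue than in each of the other strains. A gnd transcript at the WT level is not enough to raise them, since in WT itself they were lower than in aKO-Rescue by at least 5.4 on the log2 scale. A role of the gnd locus together with an inducer stays open, because genes this low in gKO and WT cannot show it. Arabinose in the aKO-Rescue cultures is a candidate explanation that was not tested independently, as the count of genes called higher against each other strain, 8 of 8, only repeats the pattern. Whether extra copies of araC, as on a plasmid, were present, alone or together with arabinose, cannot be told from these values. The araC transcript was higher than in aKO-6PGDf by 4.4, and AraC acts on distant genes such as araE, araF, araG, araH and araJ, which were higher by at least 5.35. A constitutively active AraC stays open as well and the labels name no inducer, so the differences of aKO-Rescue in sugar genes cannot be assigned to the gnd locus alone. The same holds for its other differences, such as those in ribosomal protein, RpoS, glycolysis and heat shock genes. Against WT and gKO the missing tolC reads of aKO-Rescue add to this limit, and against WT its missing ampH reads do so too.

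No reads, or at most 3, came from iprA, ampH and sbmA in any of the 9 mutant libraries. Sequencing depth does not account for this, since at least 1746 ampH reads would be found at the WT level. Missing DNA in a parent shared by the mutants and a strong decrease in transcription of an intact region cannot be told apart. The highest sum over the 3 genes in a mutant library, 3 reads, repeats the pattern, and a decrease of ampH of at least 626-fold cannot show whether DNA is present. The genes on either side kept reads but were not all unchanged. In gKO, aKO-6PGDf and aKO-Rescue, in this order, yaiW was lower than in WT by 17-, 9.25- and 24.8-fold, yaiT by 1.9-, 2.34- and 2.5-fold and ddlA by 1.09-, 1.03- and 1.74-fold. If DNA is missing, part of the difference from WT may not come from gnd in any of the 3 mutant strains.

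In aKO-6PGDf and aKO-Rescue, which lacked tolC reads, ompF was lower and marA higher than in WT. They also moved in gKO, which kept tolC reads, but by less, with ompF at -0.76 ± 0.11 and marA at 0.83 ± 0.1 against WT. In gKO tolC was lower, at 125 ± 4.86 TPM against 351 ± 9.87 TPM in WT. Complete absence of tolC does not account for the gKO part, and whether its lower level does was not tested. Absence of the gnd coding sequence as the whole cause would make ompF as low in gKO, but it was lower in aKO-6PGDf than in gKO by a log2 change of -3.56. Loss of tolC is a candidate explanation for the larger changes that was not tested independently. As a list, 18 other genes of the MarA, SoxS and Rob regulon were higher than in gKO in both strains. Of the 18, 16 were higher and 1 lower in aKO-6PGDf, and 14 were higher and 2 lower in aKO-Rescue. The larger camera p was 1.2e-05 (p = 0.0315 with an estimated correlation). Higher marA could raise these genes whatever its cause, so the list cannot single out loss of tolC. The gnd allele shared by both strains stays open and cannot be told apart from loss of tolC, because in 0 of the 12 libraries did the aKO label and the absence of tolC reads part. A strain with tolC and the aKO allele was not analysed here.

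For each comparison the 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split, 1 of 10, called 2122 genes for gKO against WT, 1895 for aKO-6PGDf against WT, 2854 for aKO-Rescue against WT, 2556 for aKO-Rescue against aKO-6PGDf, 2220 for aKO-6PGDf against gKO and 2386 for aKO-Rescue against gKO. The highest of the other splits called 0 in each of the 6. Each of those splits mixed libraries of both strains within its groups, so the differences between strains widened the spread of its fit. A count near 0 was therefore likely in advance, and these splits cannot decide whether the counts arose by chance.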
